A study of Mus musculus with 21 samples.

How the data were processed

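Total RNA was sequenced from CD31-positive cells sorted out of E0771.lmb tumours, a mouse mammary tumour line grown in wild-type mice (WT) and in mice with an inducible, endothelial deletion of Shb (KO), an adaptor protein of tyrosine kinase receptors. Per the labels' protocols, floxed Shb was deleted with a tamoxifen-activated Cre recombinase under the endothelial Cdh5 promoter, and tumours were taken between day 14 and day 16. The protocol text also names a blood-cell Cre line and a magnetic isolation of CD45-positive cells ahead of the CD31 sort, and the labels assign no sample to that line. Libraries were made with a stranded total RNA kit with ribosomal RNA depletion from 30 ng RNA and read in pairs of 150 bases, per the labels' protocols.

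The deposited table gives TPM (a read count divided by gene length and scaled to a fixed sum per library) for 45706 Ensembl genes in 21 libraries, as the authors computed it, and column totals lay between 999999.2 and 1000000.6. The genome build was GRCm38, per the submitters' processing notes, and the aligner and counting program are not given in the sources used here. TPM keeps no record of depth, so the number of reads behind a value is unknown and no counting interval is given. A transcript that takes a large share of a library lowers the TPM of every other gene in it.

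Gene coordinates were taken from the GENCODE annotation of GRCm38, in which 45143 of the gene identifiers were found. Of the gene names in the deposited file 27 had the form of dates, and these were restored from the Ensembl identifiers. Libraries were assigned to a genotype and an experiment by their column names, which match the sample titles for all but 2 columns. These 2 share a header that names KO replicate 3 of experiment 2, and they hold different values (Pearson r of log2(TPM + 1) 0.809 over 10218 genes with at least 1 TPM in both). No column names KO replicate 3 of experiment 4, which is among the sample titles. The 2 columns are called KO replicate 3a (the first) and KO replicate 3b (the second) of experiment 2. In KO replicate 3b values carry 6 decimals, like those of every column of experiment 4, and in KO replicate 3a they carry 2, like those of the other columns of experiment 2. KO replicate 3b could therefore be the sample of experiment 4 that has no column of its own, and the number and means given for experiments 2 and 4 depend on this. Its column also stands directly before those of experiment 4. In contrast, Rpph1 averaged 2207 ± 816 TPM (SD, n = 7) under experiment 2 headers, KO replicate 3b included. It averaged 28616 ± 12796 TPM (SD, n = 5) in experiment 4. On the second principal component, an axis of variation over all genes, KO replicate 3b stood at -104.8 and 3a at -120.1. The other experiment 2 libraries ran from -35.7 to -6.25 and experiment 4 from -57.7 to 35.9. The placement was not settled. Both columns entered as KO libraries of experiment 2, as their header states. Placing either in experiment 4, or leaving both out, was added as an alternative after the data were examined. The exact tests therefore ran over 21000 arrangements of the genotype labels, a different number from the one set before the data were examined, which assumed 3 KO libraries in each of experiments 2 and 4.

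Genes with at least 1 TPM in at least 10 libraries were kept, which left 13503 genes, and log2(TPM + 1) was tested with limma 3.58.1 (statmod 1.5.0, R 4.3.3) using a trended, robust variance prior and an experiment term beside the genotype. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Significance was a Benjamini-Hochberg adjusted p under 0.05. Shb and the means of marker lists were tested with an exact two-sided permutation test in which genotype labels were permuted within experiments. Gene lists, 35 of biological groups and 13 of cell types with 943 of 946 genes found in the table, were fixed before the data were examined. The biological lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. The 21 samples came from 17 tumours (9 WT and 8 KO), per the labels, which do not say which samples share a tumour, so p-values in part measure the spread between samples of one tumour. No libraries looked like copies of each other: within an experiment and genotype, correlations of log2(TPM + 1) over genes ran from 0.743 to 0.947.

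Genes named in the text are Shb, the 12 genes per direction with the largest change among those past the threshold that had the same sign in all 4 experiments and a mean log2(TPM + 1) of at least 2, and members of the fixed lists (up to 4 with the smallest p, or up to 3 with the highest mean for cell types). Where fewer genes passed, each direction was filled up to 8 genes with the smallest unadjusted p under the same conditions, and predicted gene models were left out. Amd2, Gm21887, Rpph1 and Rn7sk were chosen after their values were seen.

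The procedures were tested on simulated data with the gene variances of the real libraries. Noise was drawn once for each test and independently for each gene. Correlation between genes, differences in library purity and shared tumours were not simulated, so the rates below may not hold for the real libraries. For the comparison of KO against WT over 13503 genes, with 200 genes changed, 31.0% of genes changed by 1 on the log2 scale and 87.0% of those changed by 2 were called, together with 4 unchanged genes. For the test between experiments, 90.5% of genes changed by 3 in 1 experiment were called, together with 7 unchanged genes. For the interaction of genotype and experiment, 94.5% of genes changed by 6 in 1 experiment were called, together with 14 unchanged genes.

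Alternatives covered the pseudocount, the expression filter, the scaling of the TPM values, the experiment term, a replicate block, library weights, a covariate for leukocyte and fibroblast markers, averaging libraries to 17 assumed tumours (2 WT and 2 KO pairs of libraries with the highest residual correlations, which ran from -0.193 to 0.188), and leaving out each experiment and each library. Leaving out the 3 libraries with the lowest Pecam1 was added after the data were examined, as was a permutation test of each list mean. Tests that need read counts were not run. No library was left out of the comparisons.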

Results

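The libraries held 11 WT samples and 10 KO samples of CD31-positive cells sorted from E0771.lmb breast tumours, collected in 4 separate experiments. Experiment 1 had 3 WT and 2 KO libraries, experiment 2 had 3 and 4, experiment 3 had 2 and 2, and experiment 4 had 3 and 2. The number of genes above 0 TPM ranged from 12178 to 20526 per library. Genes of the mitochondrial genome took 1.27% to 23.01% of the TPM, and the 20 highest genes took 19.7% to 71.1%, among them small and ribosomal RNA genes such as Rn7sk. Endothelial transcripts were abundant in most libraries: Pecam1, which encodes CD31, stood at 1132 ± 525 TPM in WT (SD, n = 11) and 1263 ± 476 TPM in KO (SD, n = 10). In the 3 libraries with the lowest Pecam1, against a median of 1235 TPM, it stood at 461 TPM in WT replicate 1 of experiment 2, 242 TPM in KO replicate 2 of experiment 4 and 95.04 TPM in WT replicate 2 of experiment 4.

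Shb, the gene deleted in the KO mice, was lower in KO. Its level was 22.8 ± 16.6 TPM in KO (SD, n = 10) and 37.3 ± 18.1 TPM in WT (SD, n = 11). The experiment-adjusted log2 difference was -0.91 (SE 0.33, 95% interval -1.59 to -0.23), a level 0.532 times that of WT, with a two-sided exact permutation p = 0.0223 over 21000 arrangements. Shb (ENSMUSG00000044813) lies on chromosome 4 from 45423278 to 45532470 on the minus strand of GRCm38. In limma over all genes its adjusted p was 0.820.

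The Shb values by experiment were as follows. In experiment 2 Shb averaged 17.8 ± 11.5 TPM in KO (SD, n = 4) and 50.4 ± 12.4 TPM in WT (SD, n = 3), and in experiment 4 it averaged 6.99 ± 1.41 TPM in KO (SD, n = 2) and 27.7 ± 3.81 TPM in WT (SD, n = 3). In experiment 1 the averages were 44.5 ± 11.6 TPM in KO (SD, n = 2) and 42.1 ± 29.2 TPM in WT (SD, n = 3), and in experiment 3 they were 26.7 ± 19.4 TPM in KO (SD, n = 2) and 25.005 ± 9.55 TPM in WT (SD, n = 2). The log2 differences were 0.29, -1.59, -0.061 and -1.85 in experiments 1 to 4. With KO replicate 3b of experiment 2 placed in experiment 4, the KO averages were 20.1 ± 12.9 TPM (SD, n = 3) in experiment 2 and 8.34 ± 2.53 TPM (SD, n = 3) in experiment 4, with log2 differences of -1.42 and -1.65. A permutation test of residuals for a difference in effect between experiments gave p = 0.0601, and the interaction in limma had an unadjusted p = 0.0381 and an adjusted p = 1.00 over all genes. The tests fell on both sides of the threshold, and a difference between experiments was not established. Within an experiment, doubling the smallest possible one-sided exact p gives between 0.0571 and 0.333. Where the groups are unequal in size, the two-sided count used above could go lower. The libraries labelled KO in experiments 1 and 3 are thus not set apart from WT by Shb, and a value per gene also counts reads from exons outside the deleted part. The difference did not pass without experiment 2 (exact p = 0.227), without experiment 4 (exact p = 0.165), without KO replicates 3a and 3b of experiment 2 (exact p = 0.0688) or without the 3 libraries low in Pecam1 (exact p = 0.0748). Over the alternatives tested by exact permutation its p ran from 0.00524 to 0.297.

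**Figure D1:**
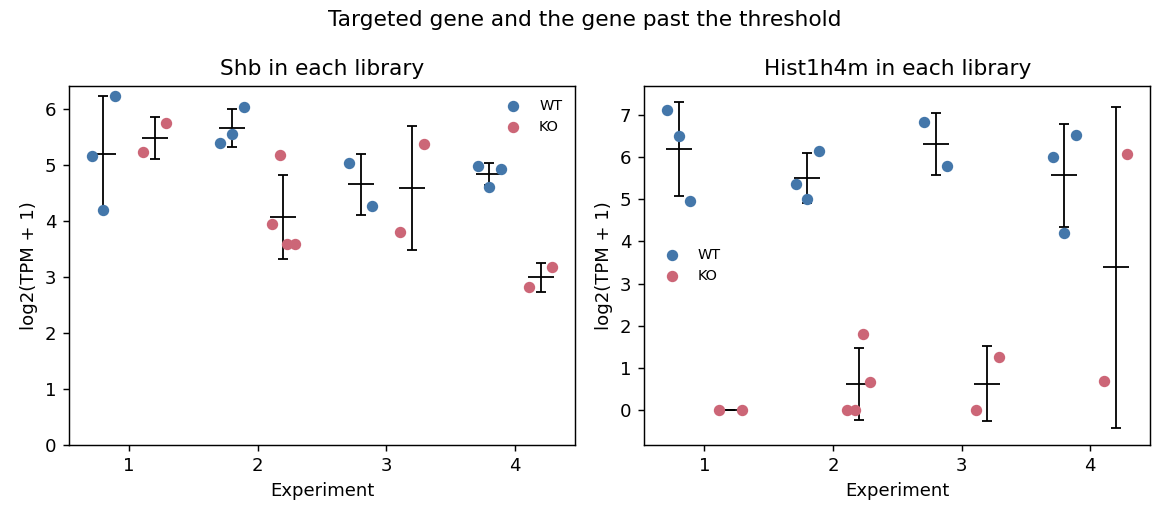
Level of Shb (left) and Hist1h4m (right) as log2(TPM + 1) in each library, by experiment, with WT in blue and KO in red. Points are libraries, and bars give the mean and SD of each genotype in each experiment. Hist1h4m lies between 17.3 and 138 TPM in the WT libraries and at or below 2.52 TPM in 9 of the 10 KO libraries.

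The comparison of KO with WT over all genes asked which transcripts of tumour endothelium depend on Shb. Hist1h4m, one of the histone H4 genes, fell in KO, from 66.9 ± 37.7 TPM in WT (SD, n = 11) to 7.17 ± 20.9 TPM in KO (SD, n = 10), a log2 difference of -4.71 (SE 0.58, limma adjusted p = 4.4e-04). It was at or below 2.52 TPM in 9 of 10 KO libraries, below every WT library, and at 66.6 TPM in KO replicate 2 of experiment 4, without which the KO mean was 0.565 ± 0.872 TPM (SD, n = 9). Hist1h4m (ENSMUSG00000069306) lies on chromosome 13 from 21811746 to 21812147. Histone H4 genes have similar coding sequences, so its level is uncertain where reads could be split among copies. Of 13503 genes tested, 1 passed, 0 higher and 1 lower in KO. At an unadjusted p under 0.05 there were 794 genes, 128 higher and 666 lower, where 675 is 5% of the genes tested. Over 99 other splits of the libraries within experiments the median was 431 and the highest 3181, and 23 of 100 splits, the real one included, gave at least 794. The excess of lower genes rested on the scaling and on single libraries: 521 of 995 such genes were higher on a common median, 544 of 1031 after quantile normalization, 313 of 1067 with rescaled TPM, and 404 of 865 without KO replicate 2 of experiment 4. The number of higher genes was 270 without WT replicate 3 of experiment 4, 76 without KO replicate 2 of experiment 1 and 68 without WT replicate 1 of experiment 2. It was 283 with KO replicate 3b of experiment 2 placed in experiment 4, 267 with KO replicate 3a placed there and 213 without both, and ran from 61 to 1037 over all 44 alternatives. The median log2 difference over all genes was -0.11, and it was -0.006 after a shift of the libraries to a common median. On that common median 2 genes passed, 1 higher and 1 lower, the higher being Pydc4 (limma adjusted p = 0.0416). Averaging libraries to 17 assumed tumours ended the Hist1h4m call at a log2 difference of -4.55 (limma adjusted p = 0.0542), as did leaving out experiment 1 (-4.26, limma adjusted p = 0.0810) or experiment 2 (-4.63, limma adjusted p = 0.332), and over all 44 alternatives its adjusted p ran from 1.8e-11 to 0.332.

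None of the other named genes passed, and their values are given as measured differences (limma adjusted p = 0.820 for each). The 8 with the smallest p toward higher levels in KO were Pydc4, Erdr1, Snx25, Mir6236, Stx1a, Phf21b, Gfod2 and Tead3. Pydc4, of the interferon-inducible PYHIN family, stood at 146 ± 75.4 TPM in KO (SD, n = 10) and 65.3 ± 25.5 TPM in WT (SD, n = 11), a log2 difference of 0.91 (SE 0.23). Erdr1, an erythroid differentiation regulator gene of the pseudoautosomal region, stood at 1142 ± 428 TPM in KO (SD, n = 10) and 573 ± 350 TPM in WT (SD, n = 11). Snx25, a sorting nexin, stood at 53.5 ± 27.7 TPM in KO (SD, n = 10) and 25.1 ± 10.8 TPM in WT (SD, n = 11). Toward lower levels stood Lsm1, Frrs1, H2-Aa, Ncaph, Apoe, H2-Eb1 and Fbln2. Fbln2, the matrix protein fibulin 2, stood at 102 ± 47.8 TPM in KO (SD, n = 10) and 181 ± 56.3 TPM in WT (SD, n = 11), a log2 difference of -0.87 (SE 0.24). Lsm1, a subunit of the mRNA decapping machinery, stood at 2.38 ± 2.10 TPM in KO (SD, n = 10) and 6.36 ± 3.19 TPM in WT (SD, n = 11). Ncaph, a condensin subunit, stood at 14.5 ± 6.93 TPM in KO (SD, n = 10) and 22.3 ± 6.90 TPM in WT (SD, n = 11).

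Genes of MHC class II presentation, which load and display peptides to helper T cells, were lower in KO as a group. All 8 measured members were lower, with a median of -1.54 relative to the median of all genes, and 7 passed when adjusted over the list alone while 0 passed over all genes. H2-Aa stood at 20.9 ± 13.2 TPM in KO (SD, n = 10) and 121 ± 195 TPM in WT (SD, n = 11), a log2 difference of -1.84 (SE 0.48). Without WT replicate 2 of experiment 3, at 699 TPM, the WT mean of H2-Aa was 62.9 ± 39.2 TPM (SD, n = 10). H2-Eb1 had a log2 difference of -2.12 (SE 0.57), H2-DMb1 of -1.97 (SE 0.54) and Cd74, the invariant chain, of -1.47 (SE 0.47). The list mean differed by -1.19, -1.29, -3.06 and -0.90 in experiments 1 to 4. The list passed camera with the preset correlation (adjusted p = 4.3e-09) and had an adjusted p = 0.493 with an estimated correlation. Pan-leukocyte markers differed by -1.26 on the log2 scale, and with leukocyte and fibroblast marker means as covariates the MHC class II list did not pass (relative median -0.28, camera adjusted p = 0.177).

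Type I interferon-stimulated genes stood higher in KO as a group, with 28 of 29 measured members above 0 and a median 0.56 above that of all genes. Rsad2 stood at 91.0 ± 33.01 TPM in KO (SD, n = 10) and 53.3 ± 23.4 TPM in WT (SD, n = 11), Ddx58, the RNA sensor RIG-I, at 173 ± 74.1 TPM in KO (SD, n = 10) and 107 ± 51.8 TPM in WT (SD, n = 11), and Oasl2 at 270.5 ± 135 TPM in KO (SD, n = 10) and 164 ± 104 TPM in WT (SD, n = 11). Ifi27l2a went the other way, with a log2 difference of -1.45 (SE 0.42). None of the members passed, over all genes or adjusted over the list alone. The list mean differed by 0.77, 0.47, 0.34 and -0.24 in experiments 1 to 4, and KO replicate 2 of experiment 4, low in Pecam1, was the lowest of the KO libraries at 4.02. The WT libraries low in Pecam1 were the lowest of the WT libraries, at 4.20 in WT replicate 2 of experiment 4 and 4.96 in WT replicate 1 of experiment 2, and without these 3 libraries the relative median was 0.46. Camera with the preset correlation gave an adjusted p = 4.5e-12, and the adjusted p = 0.966 with an estimated correlation.

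Of the 35 biological lists 12 passed camera with the preset correlation, 5 higher and 7 lower relative to all genes, and 0 passed with an estimated correlation, by fry or by exact permutation of the list mean. The other lists on the higher side were pan-endothelial identity (28 of 30 members above 0, adjusted p = 5.8e-04), immediate early genes (18 of 21, adjusted p = 0.00116), the interferon-gamma response (18 of 25, adjusted p = 0.00761) and adherens and tight junctions (14 of 20, adjusted p = 0.0332). Egfl7, an endothelial matrix protein, stood at 2436 ± 1206 TPM in KO (SD, n = 10) and 1688 ± 1021 TPM in WT (SD, n = 11). On the lower side were cytosolic ribosomal proteins (29 of 30 members below 0, adjusted p = 1.0e-07), nuclear-encoded oxidative phosphorylation (28 of 30, adjusted p = 2.2e-04), cell cycle and proliferation (26 of 30, adjusted p = 4.6e-04), glycolysis (18 of 20, adjusted p = 0.00106), cholesterol synthesis (20 of 21, adjusted p = 0.00278) and the hypoxia response (20 of 23, adjusted p = 0.0411). Gapdh, a glycolytic enzyme, stood at 1123 ± 510 TPM in KO (SD, n = 10) and 1704 ± 829.1 TPM in WT (SD, n = 11), and the replication factor Mcm3 at 33.2 ± 24.5 TPM in KO (SD, n = 10) and 50.2 ± 16.4 TPM in WT (SD, n = 11). With an estimated correlation each of these 10 lists had an adjusted p = 0.966. Leaving out 1 library ended some of these calls. Hypoxia lost its call in 10 of 21 such fits (adjusted p up to 0.294), which left out KO replicate 1 or WT replicates 1 or 2 of experiment 1, KO replicates 1 or 2 or WT replicate 1 of experiment 2, KO replicate 1 or WT replicate 2 of experiment 3, and KO replicate 1 or WT replicate 2 of experiment 4. Junctions lost theirs in 7 of 21 (adjusted p up to 0.715), which left out the same libraries of experiments 2, 3 and 4. Without WT replicate 2 of experiment 4 pan-endothelial identity (adjusted p = 0.715) and the interferon-gamma response (adjusted p = 0.320) did not pass. The same held for pan-endothelial identity without KO replicate 1 of experiment 4 (adjusted p = 0.108) and for immediate early genes without WT replicate 1 of experiment 1 (adjusted p = 0.112). Without WT replicate 1 of experiment 2 the interferon-gamma response (adjusted p = 0.0837) and cholesterol synthesis (adjusted p = 0.111) did not pass. The 23 lists that did not pass included the Notch pathway (adjusted p = 0.0587), tip cell genes and the VEGF pathway. With leukocyte and fibroblast marker means as covariates, of these 12 lists the interferon-stimulated genes and oxidative phosphorylation passed in the same direction, the endothelial identity and junction lists passed on the lower side, and the other 8 did not pass. Among these 8 the medians of hypoxia, glycolysis and cholesterol synthesis turned to above that of all genes. Of the members of the 12 lists only MHC class II genes passed when adjusted over the list alone, and 1 member of the p53 target list, which did not pass, did so.

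Markers of leukocytes and fibroblasts, cell types that a CD31 sort from a tumour can carry over, stood lower in KO. The pan-leukocyte mean was 2.39 ± 0.78 in KO (SD, n = 10) and 3.61 ± 1.70 in WT (SD, n = 11) on the log2 scale, a difference of -1.26 (SE 0.54, exact permutation p = 0.0304, adjusted p = 0.121). Macrophage and monocyte markers differed by -1.26 (SE 0.57, adjusted p = 0.121 by exact permutation), with Lyz2 at 19.4 ± 30.6 TPM in KO (SD, n = 10) and 194 ± 460 TPM in WT (SD, n = 11). Lyz2 stood at 1572 TPM in WT replicate 2 of experiment 3 and 91.9 TPM in KO replicate 1 of experiment 3. Without these libraries its mean was 55.7 ± 49.6 TPM in WT (SD, n = 10) and 11.3 ± 18.04 TPM in KO (SD, n = 9). The pan-leukocyte difference was -0.92 without that WT library. Fibroblast markers differed by -1.03 (SE 0.40, adjusted p = 0.116 by exact permutation), with Col3a1 at 19.2 ± 19.7 TPM in KO (SD, n = 10) and 60.1 ± 63.6 TPM in WT (SD, n = 11). Dendritic cell markers differed by -0.47 (SE 0.17, adjusted p = 0.116 by exact permutation), with 4 of 5 members lower. Among its 3 highest members, Cst3 differed by -0.85 (SE 0.40), Fscn1 by -0.15 (SE 0.29) and Zbtb46 by 0.33 (SE 0.33). None of the 12 cell type lists that could be measured passed by exact permutation, and B and plasma cell markers had no gene above the expression filter. Camera with the preset correlation, run beside it, called macrophage and monocyte (adjusted p = 3.6e-08) and pan-leukocyte markers (adjusted p = 8.0e-07). It also called fibroblast (adjusted p = 6.8e-04) and pericyte and smooth muscle markers (adjusted p = 0.0447). With an estimated correlation the unadjusted camera p of these lists was 0.0534, 0.0586, 0.0286 and 0.229. The remaining differences were -0.53 for pericytes and smooth muscle, -0.55 for tumour epithelium, -0.94 for skeletal muscle, -0.98 for neutrophils, 0.96 for erythroid cells, -0.27 for platelets, -0.49 for T and NK cells and -0.13 for adipocytes, with exact adjusted p between 0.186 and 0.561. Few members of several lists passed the expression filter. The skeletal muscle, neutrophil and T and NK cell values each rest on 1 gene (Mylpf, Csf3r and Lck). Erythroid cells and adipocytes rest on 3 genes each, platelets and tumour epithelium on 4 each, dendritic cells on 5 and fibroblasts on 7. In experiments 1 to 4 the pan-leukocyte difference was -0.83, -1.17, -2.92 and -0.46, and the fibroblast difference was 0.19, -1.66, -2.04 and -0.53. Leaving out KO replicate 1 or WT replicate 3 of experiment 1 let 1 list pass by exact permutation, and leaving out all of experiment 1 let 2 pass.

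**Figure D2:**
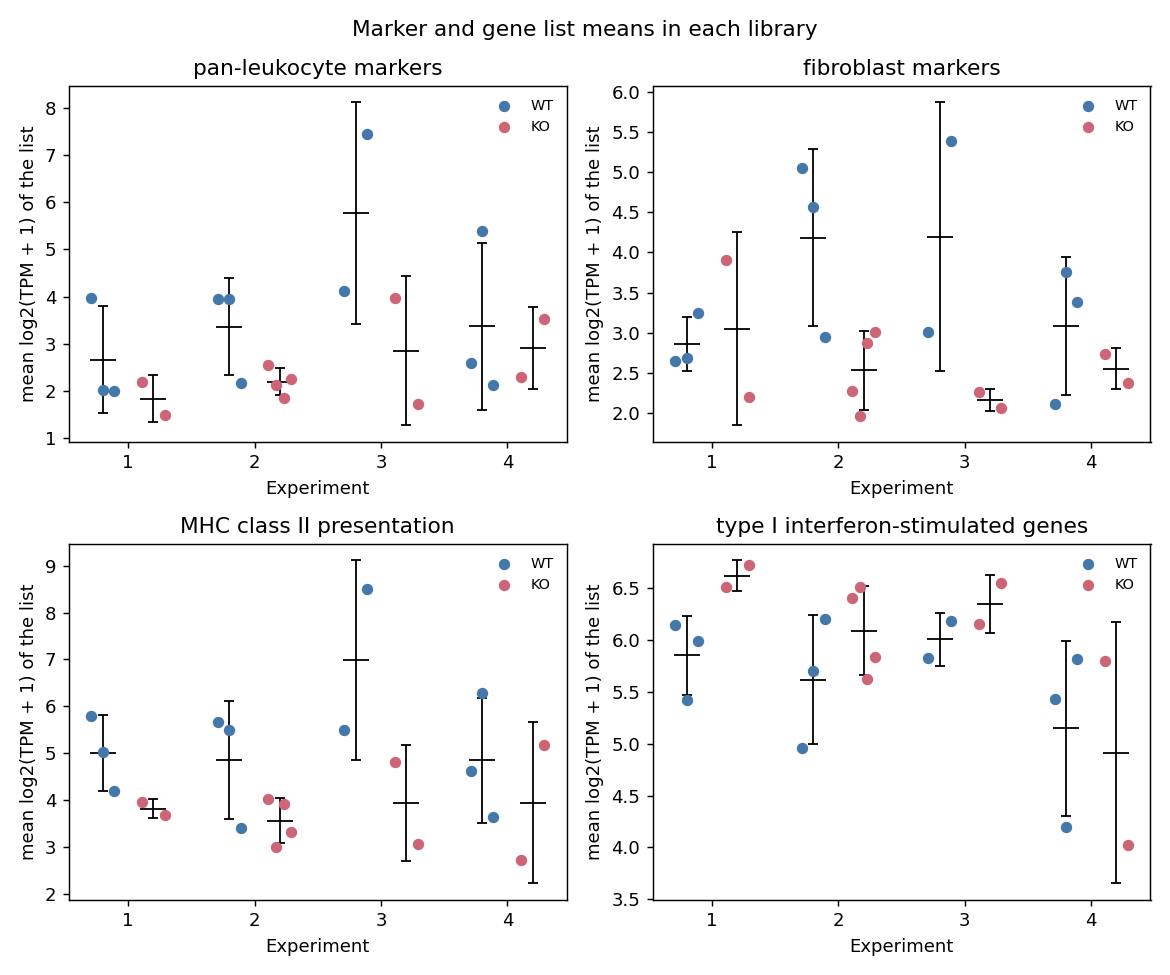
Mean log2(TPM + 1) of 4 fixed gene lists in each library, by experiment, with WT in blue and KO in red. Points are libraries, and bars give the mean and SD of each genotype in each experiment. The pan-leukocyte mean reaches 7.44 in WT replicate 2 of experiment 3, where the MHC class II mean is 8.50.

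The experiments differed from each other in many transcripts. Between experiments 3931 genes changed (limma F test, 29.1% of those tested), among them all 30 cytosolic ribosomal proteins, 22 of 30 oxidative phosphorylation genes and 17 of 25 interferon-gamma response genes. The ribosomal protein mean was 9.05, 7.43, 9.34 and 9.10 in experiments 1 to 4, and the pan-endothelial mean was 8.74, 8.01, 8.48 and 7.17. Rpph1, the RNA of ribonuclease P, averaged 2207 TPM in experiment 2 and 28616 TPM in experiment 4 (limma adjusted p = 2.7e-05). On a common median 2496 genes changed, and 2529 did without the expression filter.

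Whether the effect of genotype was shared between experiments was examined across genes, which are not independent replicates. The KO minus WT differences of the 6 pairs of experiments correlated with Pearson r between -0.057 and 0.290 and Spearman rho between -0.051 and 0.308. Their mean r was 0.114, against 0.014 as the median and -0.098 to 0.196 as the central range over 100 draws of permuted labels. The sign was the same in all 4 experiments for 14.4% of genes, against a median of 13.3% with permuted labels. For the interaction of genotype and experiment 0 genes passed in limma, and 518 had an unadjusted p under 0.05. Leaving out KO replicate 1 of experiment 2 gave 1 gene and KO replicate 1 of experiment 4 gave 27, with 1 KO library left there that is assumed to vary like the other groups, and 15 passed without the expression filter.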

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

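The tests of histone H4 copies, of other cells in KO replicate 2 of experiment 4, of marker shifts across cell types, of exchanged labels and of Shb from non-endothelial cells were chosen after the results were seen. Among the 10 KO libraries, values that stood apart from the rest were found in 11 of 61 genes and lists examined, where chance, at about 1 in 20 groups, gives 3.05. All but the Mir6236 value came from KO replicate 2 of experiment 4. The lists share genes and vary together, so the groups are not independent and 11 against 3.05 does not measure an excess over chance.

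Hist1h4m stood at 66.6 TPM in KO replicate 2 of experiment 4, with the next KO library at 2.52 TPM. The same library was apart on the low side in 9 lists. These were pan-endothelial identity at 6.19, the Notch pathway at 4.45, adherens and tight junctions at 5.64, focal adhesion and Rap1 signalling at 5.07, type I interferon-stimulated genes at 4.02, MHC class I presentation at 5.82, immune checkpoint ligands at 3.74, vessel maturation at 5.12 and SHB family adaptors at 4.02. Mir6236 stood at 56.2 TPM in KO replicate 1 of experiment 2, with the next KO library at 342.6 TPM.

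The first pattern is Hist1h4m near 0 in the other KO libraries. A smaller share of dividing cells was argued against: with the mean of 59 other histone genes as a covariate the difference was -5.06 (SE 0.71), against -4.71 (SE 0.66) without it. Reads moving to other histone H4 copies stay open, since the summed TPM of 12 other H4 genes differed by -259 in KO with a 95% interval up to 149, and the Hist1h4m loss was 57.3 TPM. For KO replicate 2 of experiment 4, transcripts of tumour or other cells are a candidate explanation: its pan-endothelial mean of 6.19 was the lowest of the KO libraries (7.49 to 8.86 in the others), while its tumour epithelial mean of 2.95 was only slightly above the next KO library at 2.86, and Krt8, of that list, stood at 69.4 TPM against at most 22 TPM. That mean rests on 4 genes. Of the other listed markers, Krt18 stood at 23.7 TPM against at most 0.45 TPM in the other KO libraries. Krt19 stood at 27.9 against 0.98 TPM and Epcam at 16.0 against 1.03 TPM. Going the other way, WT replicate 2 of experiment 4 had a pan-endothelial mean of 4.68 and Krt8 at 269 TPM. Krt18 and Epcam each stood at 0 TPM in that WT library, so the markers differ on its tumour cell content. Its Hist1h4m, at 17.3 TPM, was the lowest of the WT libraries. A variant carried by the KO line and an effect of Shb loss were not tested and remain open.

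The second pattern is the lower level of leukocyte, fibroblast and MHC class II genes in KO. With the pan-leukocyte mean as a covariate the MHC class II difference went from -1.52 (SE 0.51) to -0.43 (SE 0.23), which is consistent with carried-over leukocytes setting most of it. The sort on CD31 keeps leukocytes that carry CD31, and the protocol text places an isolation of CD45-positive cells ahead of it without saying which fraction was sorted, so the number that could carry over is unknown. A lower share of endothelial cells in WT would raise all other markers alike; the erythroid difference lay 2.23 above the pan-leukocyte one (SE 1.18), which is too imprecise to tell. Fewer leukocytes in KO tumours and lower expression in endothelial cells were not tested and stay open.

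The third pattern is the Shb difference by experiment, -1.59 and -1.85 in experiments 2 and 4 beside 0.29 and -0.061 in 1 and 3, although a difference between experiments was not established (permutation p = 0.0601, limma unadjusted p = 0.0381). Exchanged genotype labels in experiments 1 and 3 stay open: Hist1h4m was at most 1.38 TPM in their KO libraries and at least 30.2 TPM in their WT libraries, but these labels helped to pick the gene, which did not pass in experiments 2 and 4 alone (limma adjusted p = 0.351). The fit of these 2 experiments held KO replicate 2 of experiment 4, at 66.6 TPM. In it 1 other gene passed, which was not used to check the labels. Shb from non-endothelial cells stays open: over the 10 KO libraries the slope of log2 Shb on the mean of leukocyte and fibroblast markers was -1.19 (SE 0.67). Such a source calls for a positive slope. The estimate ran the opposite way but was too imprecise to decide. The fit also had no experiment term, so differences between experiments enter the slope. Incomplete deletion and reads from exons outside the deleted part were not tested.

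For the number of genes past the threshold, 2 of 100 splits within experiments gave as many as the real one, itself included, and the highest other split gave 83. This would exclude chance for a count of 1 only if the 21 libraries were independent, and they came from 17 tumours. The splits take no account of shared tumours, and 0 genes passed with 17 assumed tumours, so chance was not excluded. A split with 83 genes may point to a structure of the samples, which was not tested. It differed by -0.99 in the pan-endothelial mean, 1.44 in the pan-leukocyte mean and 3.49 in the percent of mitochondrial TPM, and no test separated these. For the lists, 50 of 100 splits called at least as many as the 12 of the real split, and the highest other called 22, so chance cannot be excluded for the count of lists. For the genes that changed between experiments, 1 of 100 regroupings, the real one, reached 3931, and the highest other gave 1666. The regroupings also take no account of shared tumours, so they do not exclude chance by themselves.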

How the results depend on the processing

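Leaving out both columns with a shared header, placing either in experiment 4 and leaving out the libraries low in Pecam1 were chosen after the data were examined. Over 44 alternatives the Hist1h4m difference stayed between -6.69 and -3.06, and the call was lost in 4. Leaving out each library in turn kept 1 changed gene and a Shb difference of -1.08 to -0.79 (exact p 0.00571 to 0.0474). It gave 8 to 15 called lists, 0 to 1 cell type lists and 0 to 27 interaction genes. Over the other alternatives 8 to 17 lists were called. The cause of the shifts below was not tested, also where fewer samples were used. Depth is unknown and its limits could not be set.

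The genes changed were 2 (1 higher) on a common median and 2 (1 higher) after quantile normalization, 8 (4 higher, 4 lower) with array weights, and 0 (0 lower) with 17 assumed tumours, without experiment 1 and without experiment 2. Whether same-numbered KO and WT samples were paired could not be told. The correlation of their deviations from the group mean ran from -0.200 to 0.356 and was over 0.1 in 2 of 8 pairs, both of experiment 4 (0.316 and 0.356). Of 8 KO samples 3 correlated best with their own number. In a group of 2 libraries the deviations mirror each other, so the 8 pairs are not separate comparisons. With the replicate block 0 genes changed (0 lower), Hist1h4m differed by -4.85 (limma adjusted p = 0.149), Shb differed by -0.49 (exact permutation p = 0.297), 17 lists were called and 2 cell type lists passed. Shb differed by -0.57 without experiment 2, -0.62 without experiment 4, -0.71 without both shared columns, -0.82 without the 3 libraries low in Pecam1, and -0.62 without those 3 and both shared columns. For cell type lists 2 passed without a filter and 2 without experiment 1. Without a filter 15 interaction genes and 2529 genes between experiments passed, and 2496 passed between experiments on a common median.

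Medians of lists relative to all genes turned with leukocyte and fibroblast covariates: pan-endothelial -0.23, arterial -0.37, venous -0.33, junctions -0.16, leukocyte adhesion -0.28, vessel maturation -0.17, hypoxia 0.11, glycolysis 0.098 and cholesterol synthesis 0.032. Basement membrane genes turned to -0.026 with array weights, -0.047 without WT replicate 2 of experiment 4 and -0.062 without the 3 libraries low in Pecam1, and venous genes to -0.17 without that WT replicate. Leaving out each library in turn gave -0.071 to 0.068 for basement membrane genes and -0.17 to 0.13 for venous genes. Tests that need read counts were not run, and experiment as a random block gave no value for gene lists or cell type lists.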

Other observations

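Amd2 and Gm21887 were chosen after their values were seen. Some genes outside the fixed lists stood apart in the same direction in all 4 experiments without passing the threshold. Gm21887 stood at 579 ± 268 TPM in KO (SD, n = 10) and 230.0 ± 187 TPM in WT (SD, n = 11), a log2 difference of 1.47 (SE 0.36, limma adjusted p = 0.820). Amd2, which encodes an enzyme of polyamine synthesis, stood at 0.255 ± 0.441 TPM in KO (SD, n = 10) and 2.26 ± 1.51 TPM in WT (SD, n = 11), a log2 difference of -1.27 (SE 0.29, limma adjusted p = 0.820). Both means of Amd2 lie close to the filter of 1 TPM, and with depth unknown its level is uncertain.

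WT libraries held more genes above 0, 17134 ± 2748 (SD, n = 11), than KO libraries, 14982 ± 2527 (SD, n = 10), with an exact permutation p = 0.0523 within experiments.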
